A study of Mus musculus with 80 samples.

How the data were processed

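Mouse embryos (B6D2F1) from in vitro fertilisation and culture (IVF) or from natural mating (NM) had been sampled in 5 tissues, and chromatin from 500 to 1000 cells per library had been immunoprecipitated in native form for H3K4me3 or H3K27me3, per the labels. The 80 libraries comprised 6 to 9 per condition, inputs included. Each of the 10 conditions (5 tissues, 2 modes of fertilisation) has 1 segmentation that the authors deposited, which names no single library and was taken to pool all of the condition's libraries. Each assigns every 500-bp step of the genome to 1 of 4 named states: none, H3K4me3, H3K27me3 or both. The deposited values are thus categories with no score, count or p-value, and the depth behind them is unknown. The submitters' processing notes name CASAVA 1.4, BWA 0.7.12-r1039 and MACS2 2.1.2 without saying what each was used for. The tool and the threshold that called the states are not given in the sources used here, nor is the way inputs entered. Whether the libraries of a condition were scaled to a common depth before calling is likewise not given, and a deeper or better enriched pool yields more marked bins.

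The notes name the builds mm9 and mm10. Genes of the mouse gene table at hand (assembly GRCm38.p6, the same as mm10) run past the end of X and of other chromosomes in the segmentations, so the segmentations were taken to be in mm9. No annotation of mm9 was used and coordinates were not converted. The promoter, gene and gene-list results laid down before the data were examined were therefore not computed, and 500-bp bins and regions given by coordinates took the place of promoters and genes. The rule for named regions was written after the files were seen and before any window value was computed: the 3 windows of 100 kb with the most gain and the 3 with the most loss of marked length in IVF, per tissue and mark. The block on chromosome 17 and the 1-Mb windows were chosen after their values were seen.

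Values were computed with Python 3.11.15 and NumPy 2.4.6, and figures were drawn with matplotlib 3.10.9. The 19 autosomes and X were used, 5277976 bins in all. A bin in the state with both marks counted for each mark. The share of bins per mark, the ratio of IVF to NM, the Jaccard index, and the share of bins shared or differing were computed per condition or pair. Their SE came from a jackknife over chromosomes. With no replicate of a segmentation, no p-value across bins was computed. Adjacent marked bins were joined into domains, called broad from 10 kb for H3K4me3 and from 50 kb for H3K27me3. The background of the Jaccard index came from 100 random rotations of the NM calls within each chromosome. The share of the genome with H3K4me3, H3K27me3 and both was compared between IVF and NM over the 5 tissue pairs with an exact two-sided sign-flip test, adjusted over the 3 values by the Benjamini-Hochberg method.

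Epiblast-type bins were those marked in NM Epi and not in NM ExE, counted in IVF ExE, with the mirror (marked in IVF Epi and not in IVF ExE, counted in NM ExE) as the comparison. The mirror gives the value expected from changes in calls only where NM and IVF have as many calls, so the ratio was also taken after the mode with more bins in a tissue had lost whole domains, narrowest first or at random, until both had as many. The same was done for ICM against TE and in the opposite directions. On simulated H3K4me3 segmentations of Epi and ExE, in which 10% of domains were dropped at random from each, so that calling was equal, the ratio to the mirror was 1.04 over 96590 bins. With 20% of the Epi-only runs planted in IVF ExE it was 2.16 over 96373 bins. The 16959 planted bins were added after the dropping. Their recovery of 100% was therefore fixed in advance and does not measure sensitivity. Dropping domains from 1 mode only, as the thinning does, was not simulated.

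The alternatives laid down beforehand that could be run were the autosomes alone, marked runs shorter than 600 bp set to unmarked, states with 1 mark only, sharing counted by domain, the mirror set, and each tissue pair left out in turn. Domains in place of bins for the epiblast-type count, overlap taken over the smaller set, and the thinning to equal bins were added after the data were seen. The marks on Y and on the mitochondrial genome entered no comparison, except that H3K4me3 on Y was compared for the question of sex ratio.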

Results

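Trimethylation of histone H3 at lysine 4 (H3K4me3), a mark of active or poised promoters, and at lysine 27 (H3K27me3), a mark of Polycomb repression, had been profiled by ultra-low-input native chromatin immunoprecipitation in mouse embryos. Embryos fertilised and cultured in vitro (IVF) were set against embryos from natural mating that developed in vivo (NM). The 5 tissues were the morula at embryonic day 2.5, the inner cell mass (ICM) and trophectoderm (TE) of the blastocyst at day 3.5, and the epiblast (Epi) and extra-embryonic ectoderm (ExE) at day 7.5. ICM and Epi belong to the embryonic lineage, TE and ExE to the extra-embryonic lineage that contributes to the placenta. The IVF segmentations are named vit for morula, ICM and TE but vitBT for Epi and ExE, and the labels do not explain these abbreviations. Whether IVF embryos of day 7.5 were handled otherwise than the earlier ones is therefore unknown. Any such handling could not be told apart from IVF in Epi and ExE. The 80 libraries, made from 500 to 1000 cells each, comprised 32 for H3K4me3, 28 for H3K27me3 and 20 inputs, with 2 to 4 libraries per antibody in each of the 10 conditions. The values come from 1 segmentation per condition, taken to pool its libraries, in which every 500-bp bin of the genome was called as unmarked, H3K4me3, H3K27me3 or both. Read depth is unknown, and no segmentation has a replicate. Errors are therefore standard errors (SE) from leaving out each of the 20 chromosomes in turn, which describe variation along the genome and not between embryos. All positions are in the mouse build mm9.

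The first question was how much chromatin carried each mark in IVF and NM embryos. Before implantation, IVF embryos had less of both marks in the morula and the ICM. H3K4me3 covered 8.13% ± 0.54 of the autosomes and X in NM morulae and 5.32% ± 0.36 in IVF morulae, a ratio of 0.654 ± 0.0035. In the ICM it covered 7.41% ± 0.45 in NM and 5.73% ± 0.35 in IVF embryos, a ratio of 0.773 ± 0.0041. The TE differed from both, with 8.0% ± 0.47 in NM and 8.25% ± 0.53 in IVF embryos. H3K27me3 covered 16.7% ± 1.0 in NM and 13.2% ± 0.87 in IVF morulae, a ratio of 0.793 ± 0.0090. The largest relative difference was in the ICM, where H3K27me3 covered 2.25% ± 0.16 in NM and 0.853% ± 0.035 in IVF embryos, a ratio of 0.38 ± 0.016. In the TE the H3K27me3 ratio was 0.709 ± 0.021. Both marks of the morula and ICM, and H3K27me3 of the TE, were lower in IVF on each of the 20 chromosomes. The morula H3K4me3 segmentation pooled 2 libraries in IVF and 4 in NM. The numbers of libraries were equal for H3K27me3 in morula, ICM and TE and for H3K4me3 in the ICM.

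At day 7.5 the balance of the marks was different. H3K4me3 covered 4.11% ± 0.19 in NM and 4.88% ± 0.25 in IVF Epi, and the IVF value was higher on 20 of 20 chromosomes. In ExE it covered 4.18% ± 0.24 in NM and 4.35% ± 0.23 in IVF embryos. The Epi segmentation of H3K4me3 pooled 4 NM and 3 IVF libraries, and that of ExE pooled 3 of each. H3K27me3 covered 11.6% ± 4.7 in NM and 10.1% ± 4.1 in IVF ExE, with lower values in IVF on all 20 chromosomes. In Epi it covered 8.57% ± 3.6 in NM and 8.79% ± 4.2 in IVF embryos. The wide errors came from X. On the 19 autosomes alone H3K27me3 was lower in IVF Epi, at 4.99% in NM and 4.57% in IVF embryos, so that the direction in Epi turned when X was left out.

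**Figure D1:**
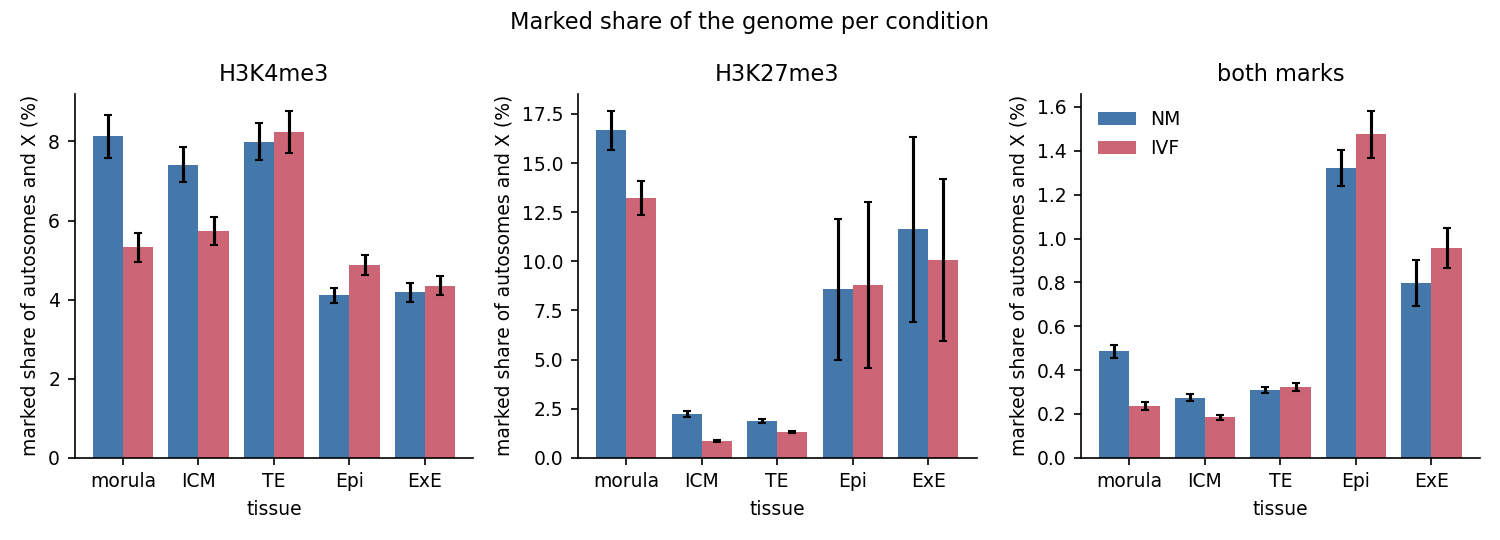
Share of the autosomes and X (percent, vertical axes) carrying H3K4me3, H3K27me3 or both marks in each tissue (horizontal axes) of NM and IVF embryos. Bars are 1 segmentation each and error bars are SE over 20 chromosomes. H3K27me3 stood at 2.25% in NM ICM and 0.853% in IVF ICM.

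Taking the tissue as the pair, H3K27me3 was lower in IVF by a mean of -1.34 percentage points ± 1.38 (SD, n = 5 tissue pairs), in 4 of 5 tissues, with p = 0.125 in an exact two-sided sign-flip test. Without X it was lower in 5 of 5 tissues, by a mean of -1.41 points ± 1.29 (SD), with an exact p = 0.063, the smallest that 5 pairs allow. The p adjusted over the 3 values tested (Benjamini-Hochberg) was 0.375 with X and 0.1875 without it, from the same exact test. H3K4me3 differed by a mean of -0.662 points ± 1.52 (SD, exact p = 0.5, adjusted 0.75), lower in 2 of 5 tissues. Without the morula the mean was -0.125 points for H3K4me3 and -0.816 points for H3K27me3. The share with both marks differed by -0.0018 points ± 0.17 (SD, exact p = 1). None of these tests could reach 0.05.

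The next comparison was whether the same places were marked. For H3K4me3 the nearest segmentation to each of the 10 conditions was that of the same tissue from the other mode of fertilisation. The Jaccard index (bins marked in both over bins marked in either) between NM and IVF was 0.572 in morula, 0.613 in ICM, 0.706 in TE, 0.555 in Epi and 0.557 in ExE. Rotating the NM calls along each chromosome gave at most 0.0517 in these comparisons. IVF morulae carried H3K4me3 at 60.2% ± 0.37 of the NM bins, and 92.0% ± 0.29 of the IVF bins were also marked in NM. For H3K27me3 the index was 0.663 in morula, 0.706 in Epi and 0.661 in ExE, while rotated calls gave at most 0.0997, 0.268 and 0.257. On the autosomes alone it was 0.615 in Epi and 0.556 in ExE. It was lowest in ICM, at 0.187 ± 0.0052, and in TE, at 0.313 ± 0.0047. NM ICM lay closer to NM TE (0.321), and IVF ICM closer to IVF TE (0.315), than ICM did to ICM. The numbers of bins limit the index between NM and IVF ICM to 0.38 at most. As a share of the smaller set, NM ICM overlapped NM morula at 0.644, IVF ICM at 0.572 and NM TE at 0.537, and IVF ICM overlapped NM TE at 0.639 and IVF TE at 0.610. On this measure NM ICM lay closer to IVF ICM than to either TE, the reverse of the Jaccard order. Only the morulae, which had the largest H3K27me3 sets, overlapped NM ICM more. IVF ICM remained closer to either TE than to NM ICM. IVF ICM retained H3K27me3 at 21.7% ± 0.71 of the NM ICM bins. Of the bins with H3K27me3 alone in NM ICM, 82.5% had neither mark in IVF ICM.

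**Figure D2:**
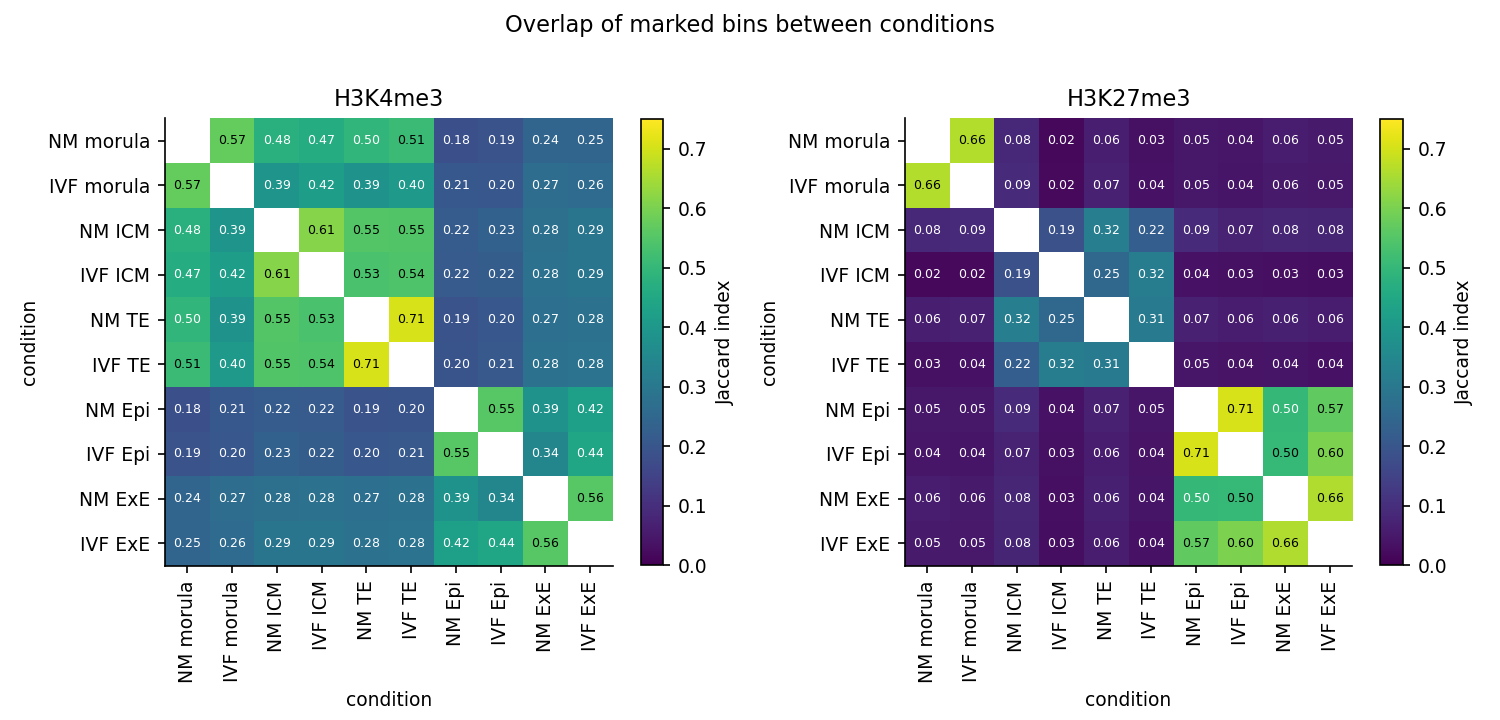
Jaccard index of marked 500-bp bins between all pairs of the 10 conditions (both axes), for H3K4me3 and H3K27me3; colour and numbers give the index. For H3K4me3 each condition overlapped most with its own tissue (0.555 to 0.706), whereas for H3K27me3 NM and IVF ICM stood at 0.187, of at most 0.38 possible with their numbers of bins.

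Broad domains of both marks were fewer in IVF morulae and ICM than in NM. In TE this held for H3K27me3 and not for H3K4me3. H3K4me3 domains of at least 10 kb numbered 4033 in NM and 1711 in IVF morulae, and 3489 in NM and 2368 in IVF ICM. TE had 4084 in NM and 4147 in IVF embryos. H3K27me3 domains of at least 50 kb numbered 1910 in NM and 1508 in IVF morulae. In ICM there were 23 such domains in NM and 0 in IVF embryos, and in TE 7 and 0. In the morula, broad domains held a similar part of the H3K27me3 length in both modes, 42.5% in NM and 42.0% in IVF. For H3K4me3 of the morula these parts were 34.0% and 18.7%. Of the 26398 windows of 100 kb, 722 had at least 20 kb less H3K4me3 in IVF morulae and 0 had as much more. In ICM, 591 windows had at least 20 kb less H3K27me3 in IVF and 1 had as much more.

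The windows with the greatest differences were named by rank. In the morula, H3K4me3 covered 83.5 kb of positions 121700001 to 121800000 on chromosome 14 in NM and 25 kb in IVF embryos. On chromosome 13, positions 44800001 to 44900000 had 95.5 kb in NM and 39.5 kb in IVF morulae. The adjoining window, 44900001 to 45000000, led the ICM list with 87 kb in NM and 38.5 kb in IVF embryos. The greatest H3K27me3 losses of the morula were equal, at 61300001 to 61400000 on chromosome 12, with 73 kb in NM and 8 kb in IVF embryos, and at 23500001 to 23600000 on chromosome 14, with 85.5 kb and 20.5 kb. In the opposite direction, 77600001 to 77700000 on chromosome 18 had 4.5 kb in NM and 59 kb in IVF morulae. For H3K27me3 in the ICM, 150500001 to 150600000 on chromosome 7 had 85 kb in NM and 2.5 kb in IVF embryos, and in TE the same window had 41 kb and 0 kb. That window was covered over 100 kb in Epi and ExE of both modes. The next windows of the ICM were 43400001 to 43500000 on chromosome 9, with 82.5 kb against 7 kb, and 68100001 to 68200000 on chromosome 11, with 86 kb against 12 kb. In TE, H3K27me3 differed most on X at 100900001 to 101000000, with 87 kb in NM and 28 kb in IVF embryos. The leading H3K4me3 gain in IVF TE was at 31300001 to 31400000 on chromosome 2, with 27 kb in NM and 55 kb in IVF embryos. What genes these windows hold was not analysed, since no annotation of mm9 was used.

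Bins with both marks resemble the bivalent state known from developmental regulator genes, but each mark came from separate libraries of many cells. The 2 marks of a bin need not lie in the same cell. Chromatin with both marks in the same bin was most extensive at day 7.5. It covered 1.32% ± 0.083 in NM and 1.48% ± 0.11 in IVF Epi, and 0.798% ± 0.10 in NM and 0.957% ± 0.093 in IVF ExE, higher in IVF on 19 of 20 chromosomes in ExE. In the morula it covered 0.486% ± 0.031 in NM and 0.237% ± 0.017 in IVF embryos, and in the ICM 0.274% ± 0.015 and 0.184% ± 0.0099. Relative to independent placement of the marks within each chromosome, bins with both marks were depleted in the morula, at 0.347 ± 0.017 of the expected number in NM and 0.324 ± 0.019 in IVF. They were enriched in ICM, at 1.57 ± 0.11 in NM and 3.68 ± 0.19 in IVF. In TE the values were 2.01 ± 0.15 and 2.93 ± 0.15. In Epi, on the autosomes, they were 5.81 in NM and 5.86 in IVF, and in ExE 2.18 in NM and 3.09 in IVF. The expected number falls with the calls of either mark, so a higher ratio need not mean more bins with both marks. In the ICM, 3.70% of H3K4me3 bins in NM and 3.21% in IVF also carried H3K27me3. Bins with both marks in IVF ExE overlapped those of NM Epi (0.462) more than those of NM ExE (0.406).

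The series asks about ectopic marks in extra-embryonic tissue, so the lineages were compared within each mode. Epi and ExE were more alike in IVF than in NM embryos. Their H3K4me3 Jaccard index was 0.386 in NM and 0.443 in IVF, a difference of 0.0566 ± 0.0019. For H3K27me3 it was 0.499 in NM and 0.601 in IVF, a difference of 0.102 ± 0.043, and on the autosomes alone 0.353 and 0.411. For both marks together it was 0.321 and 0.45, a difference of 0.128 ± 0.012. Each index was higher in IVF on 20 of 20 chromosomes. The numbers of H3K27me3 bins in Epi and ExE were less equal in NM than in IVF, which by itself lowers the NM index. As a share of the smaller set, the H3K27me3 overlap was 0.785 in NM and 0.806 in IVF, a smaller rise. For H3K4me3 this share was 0.562 in NM and 0.651 in IVF. By the Jaccard index, the ICM and TE of the blastocyst did not show this for either mark. The H3K4me3 index was 0.549 in NM and 0.544 in IVF, and the H3K27me3 index 0.321 and 0.315. The differences were -0.0043 ± 0.0039 and -0.0060 ± 0.0083. For bins with both marks, ICM and TE were more alike in IVF, at 0.282 in NM and 0.323 in IVF, higher on 17 of 20 chromosomes. The numbers of bins in ICM and TE were less equal in IVF than in NM, which by itself lowers the IVF index. As a share of the smaller set, ICM and TE overlapped more in IVF. The shares were 0.736 in NM and 0.859 in IVF for H3K4me3, and 0.537 and 0.610 for H3K27me3. Whether ICM and TE were more alike in IVF thus depends on the measure.

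Bins with H3K4me3 in NM Epi and not in NM ExE (95111 bins, 47.6 Mb) were then counted in IVF ExE. The mark was present there at 25478 of them (12.7 Mb), or 26.8% ± 0.64. Because a set chosen for lacking a mark gains it by chance, the mirror count was taken: of 107891 bins with H3K4me3 in IVF Epi and not in IVF ExE, 6.77% ± 0.29 were marked in NM ExE. The ratio of the shares was 3.96 ± 0.19, and the share was above its mirror on 20 of 20 chromosomes. Of the gained bins, 66.7% lay in Epi domains that NM ExE already marked in part, and 33.3% in domains with no marked bin in NM ExE. Counted over the latter domains, the ratio was 2.54. Bins unmarked in both NM tissues gained H3K4me3 in IVF ExE at 0.869%. For bins with both marks the shares were 34.5% ± 0.72 and 6.23% ± 0.32. For H3K27me3 they were 32.4% ± 2.0 and 26.2% ± 12.3, and on the autosomes alone 30.5% ± 0.54 and 13.9% ± 0.49, a ratio of 2.20 ± 0.095. Among H3K4me3 domains of NM Epi with no marked bin in NM ExE, 14.1% of those of 1 kb or less had at least 1 marked bin in IVF ExE, and 48.1% of the 347 domains of 5 kb or more, a count that grows with the bins in a domain. By bins the shares were 12.6% and 16.9%. The mirror shares were 7.77% and 11.8% by domains, and 6.31% and 1.94% by bins. Of the gained H3K4me3 bins, 38.7% had carried H3K27me3 alone in NM ExE and 61.3% neither mark. Marks that NM ExE carried alone were found in IVF ExE less often than those it shared with NM Epi. H3K4me3 was present in IVF ExE at 54.6% ± 1.0 of the former and 87.8% ± 0.75 of the latter bins. For H3K27me3 these shares were 50.9% ± 2.9 and 91.4% ± 2.5. This order was not particular to ExE: marks shared with the other lineage were found again 1.61 and 1.80 times as often as the rest in ExE, and 1.30 to 5.56 times in ICM, TE and Epi. In the blastocyst, ICM-type H3K4me3 bins were marked in IVF TE at 25.7% ± 0.69, against a mirror share of 26.9% ± 0.45, and ICM-type H3K27me3 bins at 11% ± 0.46 against 36.6% ± 1.3. In the other direction, ExE-type H3K4me3 bins were marked in IVF Epi at 15.2% ± 0.27 against a mirror share of 7.99% ± 0.18. For ExE-type H3K27me3 the shares were 18.1% ± 10.9 and 19.3% ± 2.2, and on the autosomes alone 7.18% ± 0.53 and 20.9% ± 1.7. TE-type bins were marked in IVF ICM at 16.1% ± 0.25 against 32.2% ± 0.56 for H3K4me3 and 17% ± 0.62 against 37.8% ± 1.8 for H3K27me3. The mirror is a fair comparison only where NM and IVF have as many calls. After thinning to equal numbers of bins over the autosomes and X, the ratio for Epi-type H3K4me3 bins in ExE was 2.49 to 3.53. For Epi-type H3K27me3 it was 1.86 to 2.25, against 1.24 ± 0.93 as called on the same chromosomes. The ratio turned to 0.509 to 0.775 for ExE-type H3K4me3 in Epi. It also turned for TE-type bins in ICM, to 1.34 to 1.5 for H3K4me3 and 1.46 to 1.83 for H3K27me3. Thinning took domains from NM in ICM, which by itself raises this ratio. For H3K4me3 in Epi it took them from IVF, which lowers the ratio. For H3K27me3 in ExE it took them from NM, which raises it. What such thinning gives without any change was not simulated, so the direction of the turned ratios is undecided.

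**Figure D3:**
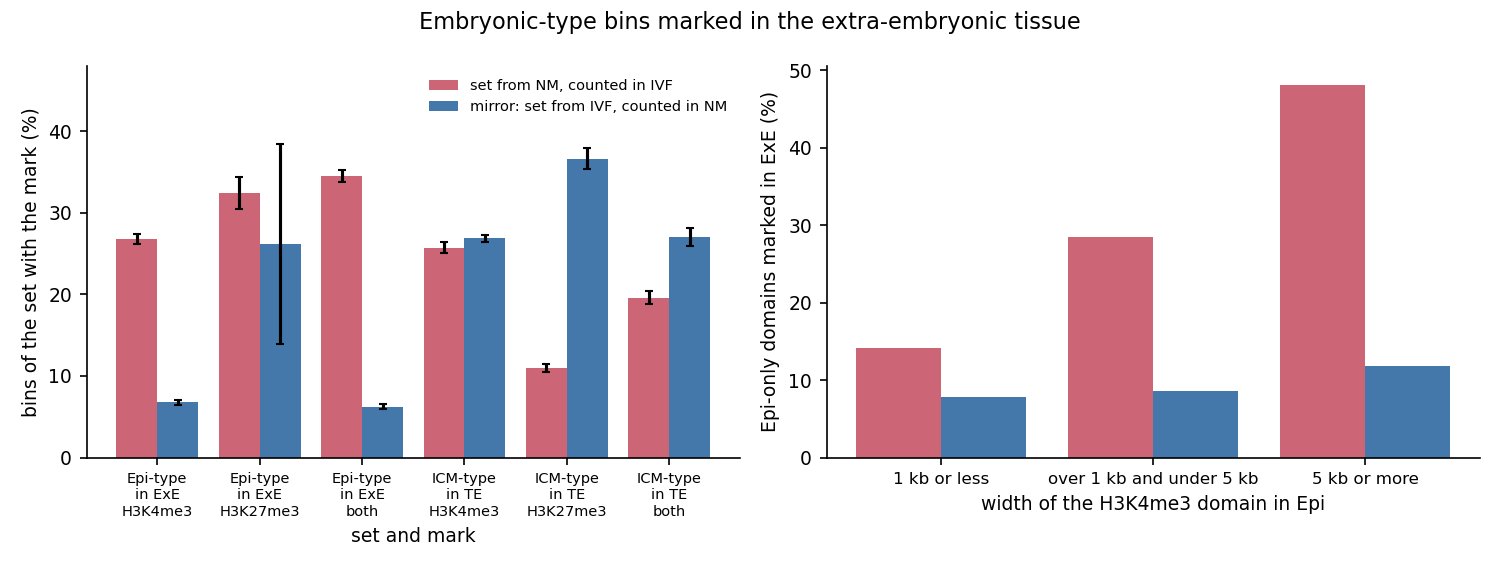
Left, share of embryonic-type bins (percent, vertical axis) carrying the mark in extra-embryonic tissue, by set and mark (horizontal axis), with error bars giving SE over chromosomes. Right, share of Epi-only H3K4me3 domains (percent) with a marked bin in ExE, by domain width, without error bars. Red bars take the set from NM and count it in IVF, blue bars are the mirror; 26.8% against 6.77% of Epi-type H3K4me3 bins were marked in ExE.

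The windows with the greatest H3K4me3 gain in IVF ExE were places already covered by H3K27me3 in both modes and by H3K4me3 in Epi. At 96100001 to 96200000 on chromosome 11, H3K4me3 covered 20 kb in NM and 76 kb in IVF ExE, and 89 kb in Epi of either mode, while H3K27me3 covered 100 kb in ExE of both modes. At 52100001 to 52200000 on chromosome 6 it covered 39.5 kb in NM and 93 kb in IVF ExE, and 100 kb in Epi of both modes. At 74500001 to 74600000 on chromosome 2 it covered 27.5 kb in NM and 78.5 kb in IVF ExE, and 93 kb in NM Epi. Of all windows, 15 had at least 20 kb more H3K4me3 in IVF ExE and 2 had as much less. For H3K27me3 in ExE, 81 windows had at least 20 kb more and 793 at least 20 kb less in IVF. Among the gains, 74800001 to 74900000 on chromosome 1 had 37 kb in NM and 83 kb in IVF ExE, and 88900001 to 89000000 on chromosome 4 had 8 kb and 52.5 kb. These windows had 77 kb and 60.5 kb in NM Epi.

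The 3 windows with the greatest H3K27me3 loss in IVF ExE all lay on chromosome 17, at 5000001 to 5100000, 5200001 to 5300000 and 8200001 to 8300000, each with 100 kb in NM and 0 kb in IVF ExE. They belonged to a block described after its values were seen. Of 22 autosomal 1-Mb windows with H3K27me3 over at least 50% in any day-7.5 condition, 11 lay on chromosome 17 between 3000001 and 15000000. Over that block H3K27me3 covered 72.8% (8.73 Mb) in NM ExE and 55.6% (6.67 Mb) in IVF ExE, but 8.69% in NM Epi, 6.23% in IVF Epi and 1.78% in NM TE. Choosing windows by their highest condition favours that condition, so the difference between NM and IVF over this block has no independent check. The largest differences were at 7000001 to 8000000, with 71.85% in NM and 30.2% in IVF ExE, and at 13000001 to 14000000, with 56.45% in NM and 16.8% in IVF ExE. Chromosome 17 was the autosome with the highest H3K27me3 share in ExE, at 17.5% in NM and 13.5% in IVF embryos.

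X had a larger share of its length under H3K27me3 at day 7.5 than any autosome. The inactive X of female cells is known to be coated with the mark. It covered 61.6% of X in NM Epi and 71.4% in IVF Epi, against autosome medians of 4.92% and 4.3%. In ExE it covered 80.5% of X in NM and 70.6% in IVF embryos, against autosome medians of 7.01% and 5.91%. In the morula and the blastocyst H3K27me3 covered 0.795% to 3.18% of X. Of the 357 windows with at least 20 kb more H3K27me3 in IVF Epi, 343 were on X. The foremost was 76600001 to 76700000, with 8.5 kb in NM and 100 kb in IVF Epi. The greatest H3K27me3 losses of IVF Epi were at 114500001 to 114600000 on chromosome 6 and 34800001 to 34900000 on X, each with 85 kb in NM and 4 kb in IVF. The second of these had 93 kb in NM and 1 kb in IVF ExE. On X, 153 of the 163 complete 1-Mb windows beyond the first 3 Mb were lower in IVF than in NM ExE, with a median change of -6.75 points. In Epi, 93 of these windows were higher and 61 lower in IVF, with a median change of 0.75 points.

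**Figure D4:**
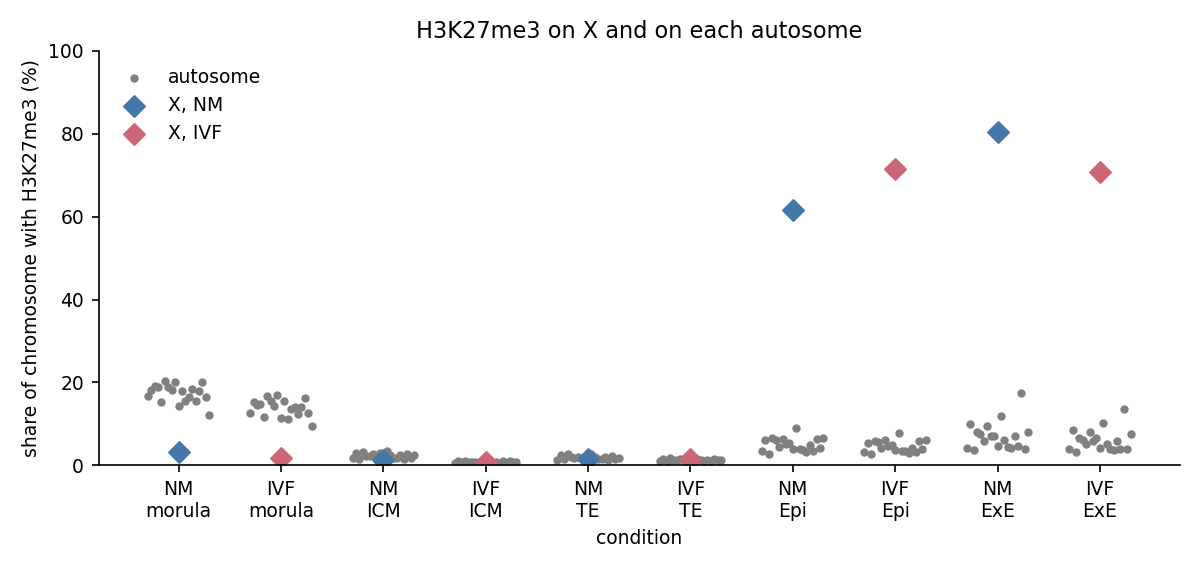
Share of each chromosome (percent, vertical axis) carrying H3K27me3 in the 10 conditions (horizontal axis); grey points are the 19 autosomes and diamonds are X. At day 7.5 X stood at 61.6% to 80.5% and the autosome medians at 4.3% to 7.01%.

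**Figure D5:**
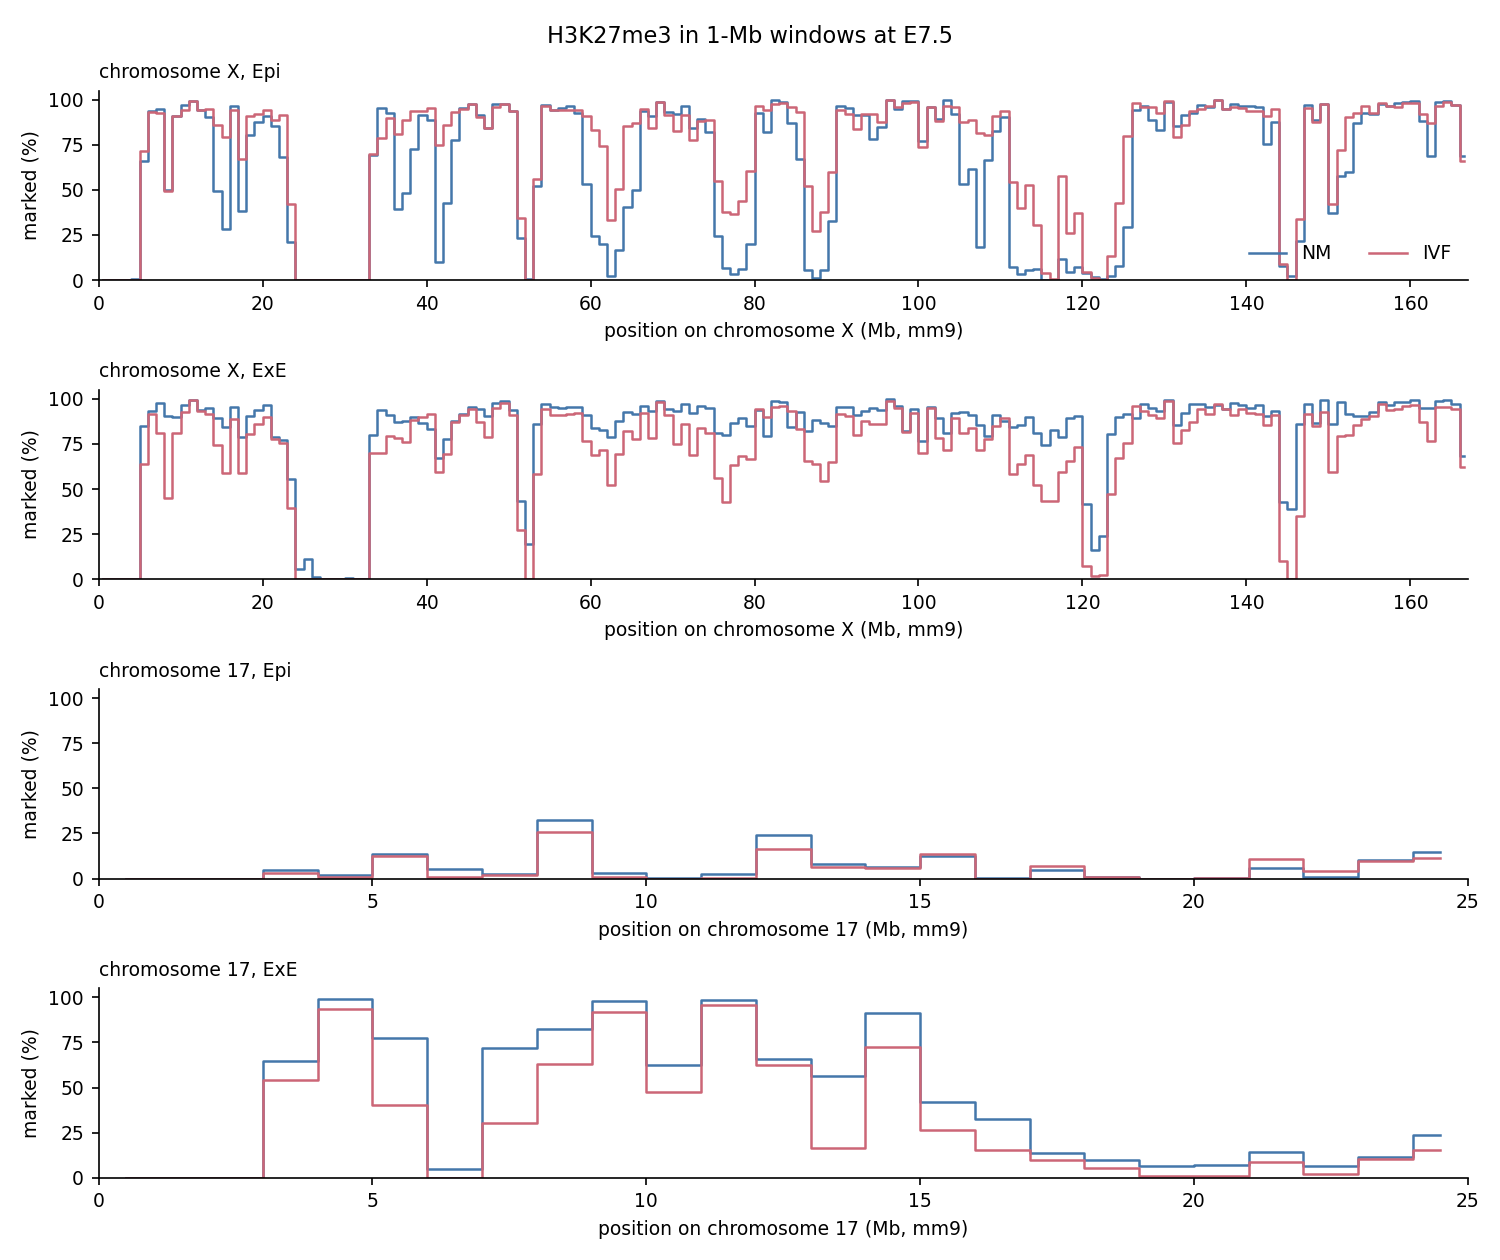
Share of each 1-Mb window (percent, vertical axes) with H3K27me3 along X and along the first 25 Mb of chromosome 17 (horizontal axes, Mb, mm9) in Epi and ExE of NM and IVF embryos. The block at 3000001 to 15000000 on chromosome 17 was covered over 72.8% in NM ExE and 55.6% in IVF ExE.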

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

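The test against random changes of calls was chosen before its value was seen, and all other tests of explanations below only afterwards. In IVF ExE, Epi-type bins carried marks more often than the mirror count. Random changes of calls gave a ratio to the mirror of 1.04 in the simulation, where calling was equal in NM and IVF. For H3K4me3 the ratio was 3.96 ± 0.19 as called and 2.49 to 3.53 after thinning to equal numbers of bins. Equal random changes in both modes therefore do not account for the H3K4me3 gain. Changes that differ between the modes are not excluded, since thinning of 1 mode moved ratios of other lineage sets across 1. More calls overall do not account for the autosomal H3K27me3 gain, since that mark was called less in IVF ExE (0.858 of the NM bins) and its Epi-type ratio was 2.20. This test was first written for autosomes and X, where the ratio was 1.24 ± 0.93 and would not have decided. H3K4me3 was called more often in IVF ExE (1.04 of the NM bins), so this test leaves more calls open for H3K4me3. Epiblast cells within the IVF ExE sample may account for the gains of both marks. As such cells would require, the share of Epi-only H3K4me3 domains with any gained bin rose with domain width. It was 3.41 times as high at 5 kb or more as at 1 kb or less (1.52 in the mirror). The share of their bins was 1.34 ± 0.11 times as high (0.308 in the mirror), and both marks gained. A change of the ExE chromatin itself under IVF would give the same values and stays open as untested, since no value at hand separates cells from cell mixtures.

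IVF morulae and ICM had fewer marked bins than NM, for which fewer pooled libraries cannot be the reason in H3K27me3 of morula and ICM and H3K4me3 of ICM, since the numbers were equal and the highest of the 3 ratios was 0.793. For H3K4me3 of the morula, with 2 against 4 libraries and a ratio of 0.654, library number and fertilisation cannot be told apart, since they differ together. Weaker enrichment or a stricter effective threshold in IVF is left open for both marks of the morula and H3K4me3 of the ICM: NM bins were found again 1.92 to 3.76 times as often in wide as in narrow domains, but for H3K4me3 1.48 to 2.06 times also in TE, Epi and ExE, where IVF had no fewer bins, and H3K27me3 had no such tissue on the autosomes, so the values do not decide. For H3K27me3 of the ICM the evidence was mixed: that ratio was 0.888 ± 0.020, but bins also marked in NM TE were found again 5.56 times as often as the others, with no H3K27me3 set of undiminished size to compare. An effect of fertilisation and culture in vitro is open and untested against library quality.

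H3K27me3 on X was higher in IVF Epi and lower in IVF ExE than in NM. A change of all chromosomes alike does not account for Epi, where the autosomes stood at 0.915 ± 0.0096 of NM while X stood at 1.16. It may account for ExE, where X, at 0.878 of NM, lay within the range of the 19 autosomes (0.770 to 0.990). Another proportion of female embryos in the pools could also move X, and H3K4me3 bins on Y stood at 0.525 of NM in Epi and 1.33 in ExE. As ratios, both are smaller than the differences on Y in tissues with little H3K27me3 on X (70 against 30 bins in morula, 24 against 63 in ICM). The values on Y therefore do not decide, and the sex ratio, which the labels do not give, cannot be told apart from fertilisation.

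Several contrasts pointed in opposite directions in paired lineages, and none of these differences was tested. For H3K4me3, IVF less NM was 0.25 percentage points in TE and -1.68 in ICM, 1.93 points apart. For bins with both marks it was 0.0157 in TE and -0.0902 in ICM, 0.106 points apart. For H3K27me3 it was 0.223 ± 0.65 in Epi and -1.55 ± 0.58 in ExE, 1.77 points apart, but without X both were negative, at -0.427 and -0.992. For H3K27me3 on X alone it was 9.86 in Epi and -9.85 in ExE, 19.7 points apart.

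Marks were also called outside the autosomes and X, where only H3K4me3 on Y entered a comparison. Between 10 (IVF ICM) and 32 (NM TE) of the 32 bins of the mitochondrial genome, which has no histones, were called as marked. H3K4me3 was called there in 23 bins in NM Epi and 0 in IVF Epi. On Y, H3K4me3 was called in 24 bins in NM ICM and up to 335 in NM Epi, of 31805, and every marked bin of Y lay in its first 3 Mb.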

How the results depend on the processing

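Of 397 recomputed values without a test, 352 kept their direction and stayed within 1.5 times, 37 moved further and 8 turned. Of 23 recomputed means over tissue pairs, 20 kept their sign and 3 turned; their p could not reach 0.05 under any setting. No paired analysis was possible because the libraries of a condition, with their replicate numbers, are pooled in 1 segmentation; tissues were paired instead. Promoter windows, coverage thresholds, transcription start sites, gene sets and random gene lists were not run for lack of an mm9 annotation. Depth is unknown, so marked length and enrichment cannot be separated. Where no cause is named below, the cause was not tested.

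Without X, which held much of the H3K27me3 at day 7.5, the net H3K27me3 change in Epi turned to -21113 bins. H3K27me3 bins numbered 246982 and 225869 in NM and IVF Epi and 345668 and 296596 in ExE. Gained Epi bins were 45734, shared bins 180135 in Epi and 229613 in ExE, and the net ExE change -49072. The number of bins differing between Epi and ExE was lower in IVF (-65295 bins). The ratio to the mirror was 2.20 for Epi-type H3K27me3 in ExE and 0.344 for ExE-type in Epi, with 13704 gained bins.

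With runs under 600 bp unmarked, bins with both marks gained and lost in the morula numbered 3295 and 12215. Their net change in TE was 1719, and their ICM and TE differences changed by -1843. The mean difference of that share over the tissue pairs turned to 0.0305 points (exact p = 0.75). Leaving out a tissue gave an exact p of 0.375 to 1 for both marks, turning the sign without morula (p = 0.375) or ICM (p = 0.875). For H3K27me3 the exact p was 0.125 to 0.25 with means of -1.73 to -0.816 points; for H3K4me3 it was 0.5 to 1, with means of -1.02 to -0.125. The smallest p of 4 pairs is 0.125.

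Counting single-mark states only, the net change was 3635 for H3K27me3 in Epi and 413 for H3K4me3 in ExE, and 103147 H3K4me3 bins were shared in Epi. Domains sharing any bin held 10345 bins with both marks in morula, and 58807 and 64617 H3K27me3 bins in ICM and TE. By overlap over the smaller set, chosen after seeing the data, 4 of 10 conditions were nearest to their own tissue for bins in the double-marked state, against 7 by the Jaccard index. The Epi-type H3K4me3 ratio by domains, also chosen afterwards, was 2.54.

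The mirror sets gave 7306 bins for Epi-type H3K4me3 and 2372 for both marks in ExE, 11428 and 859 for ICM-type in TE, 6414 and 30501 for ExE-type H3K4me3 and H3K27me3 in Epi, and 56349 and 15924 for TE-type in ICM.

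NM and IVF were also thinned to equal numbers of bins over the autosomes and X, narrowest domains first and at random, settings also chosen afterwards. The ratio to the mirror was then 3.53 and 2.49 for Epi-type H3K4me3 in ExE. It was 1.86 and 2.25 for Epi-type H3K27me3 in ExE (1.24 ± 0.93 as called). It was 0.515 and 0.749 for ICM-type H3K27me3 in TE. It turned for ExE-type H3K4me3 in Epi (0.775 and 0.509) and for TE-type H3K4me3 (1.34 and 1.5) and H3K27me3 (1.46 and 1.83) in ICM. For ExE-type H3K27me3 in Epi it was 1.01 and 0.774. Thinning removed domains from 1 mode only, and the ratio that this gives without any change was not simulated. The direction of these turned ratios is therefore undecided.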

Other observations

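No tests were run on the values in this part, which were chosen for description after the data had been seen. Most H3K27me3 of the morula was absent from the blastocyst in both modes. Of the morula bins, 8.69% ± 0.60 carried it in NM ICM and 1.89% ± 0.15 in IVF ICM, and 6.45% ± 0.46 in NM TE and 3.99% ± 0.27 in IVF TE. Of the H3K27me3 bins of the ICM, 64.4% ± 1.5 had been marked in the morula in NM embryos and 29.3% ± 1.7 in IVF embryos. H3K4me3 of the morula was present in the ICM at more similar shares, with 61.7% ± 0.40 of the morula bins marked in NM ICM and 61.4% ± 0.44 in IVF ICM. In TE these shares were 65.7% ± 0.45 and 73.5% ± 0.40. Of the H3K4me3 bins of the ICM, 67.7% ± 0.82 in NM and 57.0% ± 0.79 in IVF had been marked in the morula, and of those of the TE 66.8% ± 0.88 and 47.4% ± 0.63. Each share depends on the number of calls in the tissue where it is counted. By share of the genome, 2.25% of morula bins would carry H3K27me3 in NM ICM and 0.853% in IVF ICM. IVF morulae had fewer bins of both marks than NM morulae.

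Bins with both marks in Epi had different earlier states in the modes. In NM embryos 10.9% had both marks in the ICM already, 38.0% had H3K4me3 alone, 16.6% H3K27me3 alone and 34.5% neither. In IVF embryos 6.15% had both marks in the ICM, 29.2% H3K4me3 alone, 9.32% H3K27me3 alone and 55.3% neither. IVF ICM had fewer calls of both marks than NM ICM, which would by itself raise the share with neither. Over all bins, 90.6% had neither mark in NM ICM and 93.6% in IVF ICM. In ExE, 15.1% of the bins with both marks in NM and 12.8% in IVF had both in TE.

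Outside chromosome 17, broad autosomal H3K27me3 at day 7.5 included 151000001 to 152000000 on chromosome 7, with 76.25% in NM ExE, 64.7% in IVF ExE and 21.2% in NM Epi. On chromosome 8, 123000001 to 124000000 had 65.6% in NM ExE and 44.2% in IVF ExE. On chromosome 18, 37000001 to 38000000 was higher in IVF, with 43.85% in NM Epi and 50.65% in IVF Epi.

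The H3K4me3 losses of IVF Epi were led by 22800001 to 22900000 on chromosome 12, with 54 kb in NM and 0 kb in IVF Epi. They continued with 20200001 to 20300000 on chromosome 12, with 60 kb and 9.5 kb, and 85200001 to 85300000 on chromosome 1, with 68 kb and 19.5 kb. In NM ExE the same windows had 11 kb, 20 kb and 7 kb.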
